A study of Arabidopsis thaliana with 12 samples.

How the data were processed

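RNA was sequenced from whole seedlings of Arabidopsis thaliana, grown for 8 days in MGRL medium with 0.2% agarose and 1% sucrose, per the labels. Seedlings were moved to liquid medium for 3 h and then treated with mock or chitin for 3 h. The chitin dose is given as 40 mM in the design text and as 40 µM in the treatment protocol, and which is right is not given in the sources used here. Libraries were made from poly(A)-enriched RNA (1 µg of total RNA) with a directional kit. The 12 libraries form 4 groups of 3 by genotype (Col-0 or mapkkk5-1) and treatment (mock or chitin), as the titles and characteristics give them, and the design text speaks of 3 independent experiments.

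The authors deposited a table of raw read counts per gene, with whole numbers and no normalization, for all 12 libraries. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.5, TopHat2 2.0.10 and HTSeq 0.6.1 and the genome build TAIR10, without their settings. The strand setting and the overlap mode of the counting are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as the Rubisco small subunit genes, CYP71A12 and CYP71A13, the glutathione transferase genes and the WAK and CRK kinase genes, could therefore be divided or dropped in ways that cannot be checked from counts per gene, and their values are uncertain to that extent. The counts also do not show which part of a gene the reads came from, which matters for MAPKKK5 in the mutant.

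The table lists 32678 genes, 7389 of them with no read in any library. Of the identifiers, 31912 matched the NCBI RefSeq annotation of TAIR10.1, which was used for symbols, positions and neighbouring genes. The unmatched ones, with 279 organelle genes among them, hold 0.4% of the reads. The table carries no coordinates, so positions are those of TAIR10.1. Total counts per library were 15455836 to 20179428 reads, the 10 most abundant genes held 2.82 to 3.55% and organelle genes 0.32 to 0.47%. At these depths 3 reads, the limit that a count of 0 allows, correspond to 0.149 to 0.194 CPM; this covers counting error only. All 12 pairs of replicates differed by far more than sampling noise (chi-square per degree of freedom 11.07 to 27.39), so no libraries were merged. Separate preparations of 1 RNA could differ as much, and the independence of the libraries rests on the labels.

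Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups (20994 genes), library sizes were scaled by TMM (factors 0.971 to 1.034), and 1 quasi-likelihood model (glmQLFit and glmQLFTest) with the 4 groups was fitted to all 12 libraries, with 8 residual degrees of freedom. Tests covered chitin in Col, chitin in mapkkk5, mapkkk5 against Col in mock and in chitin, the difference between the chitin responses, and the average response. Calls used a Benjamini-Hochberg adjusted p below 0.05 with no fold limit. The standard error of a log2 fold change was taken as its absolute value divided by the square root of the quasi-likelihood F statistic. CPM values use TMM-scaled library sizes. Differences are mapkkk5 minus Col and chitin minus mock.

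Before the data were examined, 22 gene lists with 368 genes were written from general knowledge, with markers of root, stomatal lineage and phloem among them. All 368 identifiers are in the table, and 365 passed the filter. For 359 of them the annotation held the symbol or a name containing it, for 7 it gave no name and for 2 another name. No gene was left out for its name. Lists were tested with limma 3.58.1 on edgeR's values, by camera with a preset correlation of 0.01 and with an estimated one, and by fry, with adjustment over the lists within a comparison; the counts of members are given over all genes and adjusted over the list alone. Genes named in the text were chosen by a rule fixed in advance: per comparison up to 8 raised and 8 lowered genes with a symbol, the largest fold changes among called genes with a mean log2 CPM of at least 1 and no overlap between groups, up to 2 raised and 2 lowered members per list with the smallest p, or the member with the smallest p where none passes, and MAPKKK5 with 5 measured neighbours on each side. Exceptions are marked in the text. To test for a general weakening, genes called in the averaged response with an absolute log2 fold change of at least 1 were taken, which favours neither genotype, and the difference of responses was tested over them with fry and described by a total least squares slope. The adjustment of fry over the raised and lowered sets and the exact sign-flip tests over the 3 experiments were chosen after the results were seen.

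Replicate numbers 1 to 3 occur in every group. To see whether they mark the shared experiments, the deviations of each library from its group mean (log2 CPM) were correlated. All 12 same-numbered pairs within the comparisons of 2 groups correlated above 0.1 (0.16 to 0.51), the median over all 18 same-numbered pairs was 0.30 and over differently numbered pairs -0.16, and 1 pair, Col mock 1 and mapkkk5 chitin 1, was at -0.04. Without TMM scaling and with another filter, 11 of the 12 pairs were above 0.1. In that check mapkkk5 chitin 1 correlated at 0.07 with mapkkk5 mock 1 and at 0.26 with mapkkk5 mock 2. Together with the design text, the numbers were taken to pair the libraries, and a fit with the replicate number as a block (6 residual degrees of freedom) is given beside results that it changes. The seedlings of 1 experiment may have been grown together, so the unblocked p-values measure the spread between experiments as well.

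The pipeline was tested on simulated counts drawn from these means and library sizes with 80, 80 and 40 genes changed 1.5-, 2- and 4-fold. In a comparison of 2 groups (20862 genes) 22.5%, 71.2% and 97.5% of these were recovered, with 10 false among 124 calls. For the difference of responses (20879 genes) the shares were 3.75%, 46.2% and 85.0%, with 7 false among 81 calls. A simulated response reduced to 0.8 of that of Col gave a median difference of -0.38 and a fry p of 6.03e-10, and an unreduced one -0.01 and 0.935. The simulated counts were drawn separately for each gene and library, without spread shared by genes or by the libraries of 1 experiment. They therefore do not show how well fry would find such a weakening in the real libraries. In 200 random lists of 20 genes, camera gave an unadjusted p under 0.05 for 5.0% in the chitin comparison in Col and 1.5% in the difference of responses. Genes drawn at random need not vary together as members of a list do, so this check does not cover the preset correlation for such lists.

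The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, no low-count filter, a filter of at least 5 CPM in at least 3 libraries, the replicate block, only the groups compared, a test against an absolute log2 fold change of 1, the analysis without organelle genes, and leaving out each library or each replicate number in turn. After the data were seen, a fit with a covariate was added, the log2 of the summed CPM of 18 seed genes plus 0.5, because the summed level of these genes was higher in 5 libraries than in the others. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to read the table and draw the plots. No library was left out of the main analysis.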

Results

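Gene expression was measured by RNA sequencing in whole Arabidopsis thaliana seedlings of the wild type Col-0 (written Col here) and of the mapkkk5-1 line (written mapkkk5), which is named for MAPKKK5, a gene encoding a MAP kinase kinase kinase. Seedlings of each genotype received mock treatment or chitin, a fungal cell wall polymer that plants sense as a sign of infection, for 3 h. The 4 groups held 3 libraries each, and the design text describes 3 independent experiments. Total counts per library ranged from 15455836 to 20179428 reads, so that 3 reads corresponded to at most 0.194 counts per 1000000 reads (CPM). Of 20994 genes that passed the expression filter, the first principal component, with 64.4% of the variance, separated mock from chitin libraries, and the second, with 8.8%, separated the libraries of experiment 3 from the others. Log2 fold changes are given ± SE and CPM values as mean ± SD (n = 3 libraries per group), and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. All p-values rest on 3 experiments, independent as the labels state.

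The targeted gene, MAPKKK5 (AT5G66850), lies on chromosome 5, 26695568 to 26699426, on the minus strand in the TAIR10.1 annotation. In mock libraries it was at 25.2 ± 3.19 CPM in Col and 4.33 ± 0.831 CPM in mapkkk5, a log2 difference of -2.53 ± 0.27 (adjusted p = 0.00147). Without all 4 libraries of experiment 1 no gene passed in mock, so this call was lost. In chitin libraries MAPKKK5 was at 40.9 ± 3.96 CPM in Col and 24.4 ± 9.85 CPM in the libraries labelled mapkkk5, and this difference of -0.75 ± 0.23 did not pass the test (adjusted p = 0.674). The chitin-treated libraries labelled mapkkk5 held 503, 583 and 237 reads of the gene, against 70, 97 and 61 reads in mapkkk5 mock. The groups did not overlap after chitin either, with 32.9 CPM at most in mapkkk5 and 37.5 CPM at least in Col. Within mapkkk5 the gene rose by 2.49 ± 0.27 on the log2 scale (adjusted p = 1.3e-05). In Col it rose by 0.70 ± 0.23 (adjusted p = 0.0296), a call that was lost without Col chitin replicate 1 (adjusted p = 0.0569), Col mock replicate 2 (0.0709), Col mock replicate 3 (0.0999) or Col chitin replicate 3 (0.0874). The difference between the responses was 1.79 ± 0.36 (adjusted p = 0.866 over all genes), positive in each experiment (2.24, 2.07 and 0.75; exact sign-flip test over 3 experiments, two-sided p = 0.25, the smallest it can give). Leaving out the third mapkkk5 chitin library raised the difference to 2.07 (adjusted p = 0.00883), and DESeq2 gave 1.81 (adjusted p = 0.0033). None of the 10 nearest measured genes, 5 on each side, passed the test between genotypes in mock or chitin, and their median log2 difference in mock was 0.00, from -1.76 to 0.85.

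**Figure D1:**
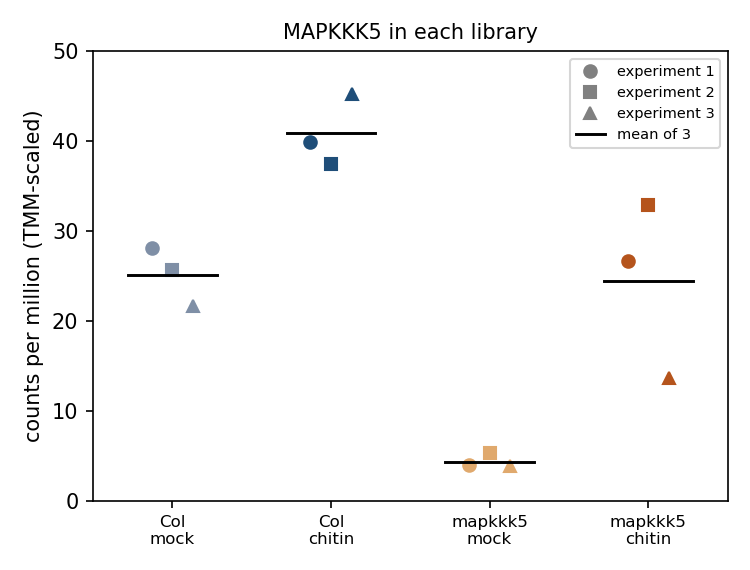
MAPKKK5 in each of the 12 libraries, in CPM on the vertical axis, for the 4 groups on the horizontal axis; circles, squares and triangles are experiments 1, 2 and 3 and black bars are means of 3 libraries. The mapkkk5 mock libraries lie between 3.81 and 5.29 CPM, and the chitin-treated libraries labelled mapkkk5 between 13.6 and 32.9 CPM.

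The first comparison asked which genes responded to chitin in the wild type. CYP71A13 (AT2G30770), an enzyme of camalexin synthesis, went from 2.00 ± 1.04 to 146 ± 29.5 CPM (log2 fold change 6.17 ± 0.34, adjusted p = 2.72e-08). The glutathione transferase gene GSTF3 (AT2G02930, 6.29 ± 0.29), the ABC transporter gene ABCG40 (AT1G15520, 6.05 ± 0.34), the peroxidase gene PER4 (AT1G14540, 6.05 ± 0.33) and the cytochrome P450 gene CYP82C2 (AT4G31970, 6.01 ± 0.46) changed by similar amounts, and PXMT1 (AT1G66700) and DMP1 by 6.14 ± 0.36 and 5.96 ± 0.34. CCOAMT was near the level of 3 reads in mock (0.213 ± 0.126 CPM) and at 23.8 ± 9.18 CPM after chitin. The lowered genes included the iron transporter gene IRT1 (AT4G19690, -2.84 ± 0.52) and the nicotianamine synthase gene NAS1 (AT5G04950, -2.56 ± 0.35), together with the aliphatic glucosinolate genes MYB29 (AT5G07690, -2.79 ± 0.35) and CYP79F1 (AT1G16410, -2.74 ± 0.62), the thalianol synthase gene THAS1 (AT5G48010, -3.12 ± 0.53) and GASA5 (AT3G02885, -2.68 ± 0.24). MES18 and RL1 fell by 2.74 and by 2.64 on the log2 scale, and all of these passed the test (adjusted p of 0.00325 or below).

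Immune gene lists fixed before the data were examined rose together in Col. Of 24 reporters of pattern-triggered immunity, 21 rose (22 adjusted over the list alone), among them the indole glucosinolate regulator MYB51 (AT1G18570, 3.32 ± 0.13) and NHL10 (AT2G35980, 5.83 ± 0.26), with a camera adjusted p of 3.47e-39. Of 26 genes of tryptophan, camalexin and indole glucosinolate synthesis, 25 rose (25 adjusted over the list alone), including PAD3 (AT3G26830), which catalyses the last step to camalexin, from 23.0 ± 4.89 to 424 ± 34.7 CPM, and the anthranilate synthase gene ASA1 (AT5G05730, 2.90 ± 0.12). The remaining member, the regulator MYB34, fell by 0.91 on the log2 scale (camera adjusted p for the list 4.32e-52). All 22 salicylic acid genes rose (22 adjusted over the list alone, camera adjusted p = 2.37e-23), led in p by PBS3 (AT5G13320), which conjugates isochorismate to glutamate, at 4.03 ± 0.18, and the transcription factor gene SARD1 (AT1G73805) at 1.97 ± 0.11. The same direction held for 21 of 25 WRKY transcription factor genes (21 over the list alone, camera adjusted p = 6.1e-20), with WRKY33 at 2.60 ± 0.15 and WRKY40 at 2.71 ± 0.16. Of 13 chitinase, glucanase and wall defence genes measured, 11 rose and 1 fell (12 and 1 over the list alone, camera adjusted p = 7.14e-09), the chitinase gene CHI by 3.64 ± 0.19, and CTL1 fell by 0.62. MAP kinase cascade genes rose in 15 of 20 cases (15 over the list alone, camera adjusted p = 7.48e-07), with MKK9 at 1.65 ± 0.14 and MEKK3 at 0.97 ± 0.09. Of 16 ethylene genes, 14 rose and ACS7 fell by 1.24 (14 and 1 over the list alone, camera adjusted p = 6.07e-07), and the ACC synthase genes ACS6 and ACS2 changed by 2.51 ± 0.14 and 3.11 ± 0.22. These 7 list results held with an estimated correlation, with adjusted p-values from 0.00486 to 0.0394. The ethylene list did not (adjusted p = 0.0529) when the level of seed storage genes was added as a covariate, an alternative chosen after the data were seen.

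Further lists moved in Col under camera's preset correlation of 0.01 but not with an estimated one. All of the lists in this paragraph passed fry in Col, with adjusted p-values of 0.0232 or below. Fry does not compare the members with the remaining genes, and 38.5% of all genes tested were called in Col. Of 25 pattern receptor and receptor-proximal kinase genes, 17 rose and 3 fell (the same counts over the list alone, camera adjusted p = 1.28e-05, adjusted p = 0.167 with an estimated correlation). The LysM protein gene LYM2 rose by 1.19 ± 0.11 and the co-receptor gene BAK1 2.14-fold, while LYM3 and LYM1 fell by 1.04 and 0.67. Phenylpropanoid and lignin genes rose in 12 of 16 cases and PAL3 fell by 0.54 (14 and 1 over the list alone, camera adjusted p = 0.0003, adjusted p = 0.393 with an estimated correlation), with CCR2 at 2.60 ± 0.21 and CAD5 at 1.38 ± 0.14. Flavonoid genes fell in 7 of 11 cases (7 over the list alone), including TT7 (-1.31 ± 0.19) and the regulator MYB111 (-1.53 ± 0.30), with a camera adjusted p of 0.00455 and an adjusted p = 0.419 with an estimated correlation. Of 24 photosynthesis genes, 8 fell (5 over the list alone, 21 with the experiments as a block), the Rubisco small subunit gene RBCS1B from 1540 ± 291 to 644 ± 180 CPM and PSBO2 by 0.94 (camera adjusted p = 0.00284, adjusted p = 0.419 with an estimated correlation). Jasmonate genes rose in 12 of 27 cases (12 over the list alone), with LOX4 at 2.73 ± 0.33 and CYP94C1 at 2.13 ± 0.29 (camera adjusted p = 0.0254, adjusted p = 0.653 with an estimated correlation). Of 12 brassinosteroid and cell expansion genes, 3 rose and 6 fell (3 and 6 over the list alone, camera adjusted p = 0.0271, adjusted p = 0.299 with an estimated correlation), and the wall genes XTH4 and EXPA5 fell by 1.22 and by 1.53.

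The other 9 lists did not stand apart from the remaining genes in Col. Counts of genes that rose and fell were 2 and 3 of 14 for abscisic acid and dehydration (camera adjusted p = 0.742), 3 and 3 of 18 for auxin (0.824), 3 and 0 of 15 for the circadian clock (0.861), 1 and 0 of 7 for heat shock (0.716), 1 and 0 of 11 for low oxygen (0.861) and 3 and 1 of 9 for reference genes (0.742). Adjusted over the list alone the counts were 2 and 3, 3 and 2, 0 and 0, 1 and 0, 0 and 0 and 3 and 1. UBQ10 rose by 0.40 ± 0.10 and EF1A fell by 0.51, so these common reference genes moved apart. With the experiments as a block, 6 clock genes rose and 3 fell. Among markers of organs and cell types, 6 root markers rose and 5 fell of 21 (6 and 5 over the list alone, camera adjusted p = 0.733), no stomatal marker of 7 changed (0 over the list alone, 0.711), and 1 phloem marker of 2 rose (1 over the list alone, 0.887). The small medians of the auxin, reference, root and phloem lists (0.09, 0.10, 0.01 and 0.10) changed sign with upper-quartile scaling, and that of the root list also with RLE scaling.

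In all, 8083 genes changed with chitin in Col, 4458 up and 3625 down, of which 1553 and 602 changed at least 2-fold. With the experiments as a block the count was 10558. Upper-quartile scaling turned the split to 3583 up and 5017 down, a shift from 55.2% to 41.7% up, since it moved the median of all genes by -0.11 on the log2 scale.

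The same comparison was made within mapkkk5. The named genes with large increases were CYP71A13 at 6.90 ± 0.38, CYP71A12 (AT2G30750) from 3.61 to 382 CPM (6.72 ± 0.35), and FOX1 (AT1G26380), an oxidoreductase gene, at 6.59 ± 0.34. GSTF3 rose by 6.71 ± 0.32, PXMT1 by 7.45 ± 0.41 and GSTU12 by 6.07 ± 0.37, while CYP82C2, at 0.151 CPM in mock and so near 3 reads in a library, reached 52.7 CPM. The lowered genes with the largest changes were IRT1 (-3.54 ± 0.50), the ferric reductase gene FRO2 (AT1G01580, -2.66 ± 0.36), NAS2 (AT5G56080, -2.82 ± 0.28), THAS1 (-2.90 ± 0.53), MYB29 (-2.86 ± 0.34), GASA5 (-2.88 ± 0.24), MLP328 (-2.85 ± 0.50) and RL1 (-2.65 ± 0.30). All passed the test with an adjusted p of 0.000863 or below.

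Immune lists rose in mapkkk5 too. Pattern-triggered immunity reporters rose in 21 of 24 cases and 1 fell (21 and 1 over the list alone, camera adjusted p = 6.07e-43), with CYP81F2 (AT5G57220), an indole glucosinolate hydroxylase gene, at 5.07 ± 0.25 and MYB51 at 3.42 ± 0.13. Tryptophan, camalexin and indole glucosinolate genes rose in 25 of 26 cases and MYB34 fell (25 and 1 over the list alone, 2.68e-56), PAD3 by 4.42 ± 0.20. Salicylic acid genes rose in 21 of 22 cases (21 over the list alone, 7.19e-20), with SARD1 at 1.82 ± 0.11 and DLO1 (AT4G10500), a salicylic acid hydroxylase gene, at 3.13 ± 0.22. WRKY genes rose in 20 of 25 cases (21 over the list alone, 3.83e-19), chitinase and wall defence genes in 11 of 13 with 1 lowered (11 and 1 over the list alone, 4.63e-11) and MAP kinase cascade genes in 15 of 20 (16 over the list alone, 6.27e-06). These 6 held with an estimated correlation, with adjusted p-values from 0.00392 to 0.0273. Ethylene genes rose in 12 of 16 cases and 1 fell (15 and 1 over the list alone, camera adjusted p = 3.13e-05, adjusted p = 0.0844 with an estimated correlation). Receptor genes rose in 16 of 25 cases and 2 fell (17 and 2 over the list alone, 3.13e-05, adjusted p = 0.182 with an estimated correlation), phenylpropanoid genes rose in 10 of 16 (11 over the list alone, 0.00141, adjusted p = 0.499 with an estimated correlation), flavonoid genes fell in 7 of 11 (7 over the list alone, 0.00141, adjusted p = 0.437 with an estimated correlation) and photosynthesis genes in 4 of 24 (3 over the list alone, 0.0188, adjusted p = 0.649 with an estimated correlation). With the block, 18 photosynthesis genes fell and 1 rose. Jasmonate genes rose in 10 of 27 cases (10 over the list alone, camera adjusted p = 0.0957, with the block 0.0467, both at the preset correlation).

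The remaining lists did not stand apart in mapkkk5. Genes that rose and fell were 3 and 5 of 12 for brassinosteroid and cell expansion (camera adjusted p = 0.26), 0 and 5 of 21 for root markers (0.26), with IRT1 and the beta-glucosidase gene PYK10 (-1.19 ± 0.26) lower, 2 and 1 of 14 for abscisic acid (0.937), 4 and 2 of 18 for auxin (0.937) and 2 and 0 of 15 for the clock (0.699). For heat shock they were 1 and 0 of 7 (0.937), for low oxygen 1 and 0 of 11 (0.735), for reference genes 3 and 1 of 9 (0.843), for stomatal markers 0 and 1 of 7 (0.735) and for phloem markers 1 and 0 of 2 (0.855). Adjusted over the list alone, counts differed for brassinosteroid (3 and 6), root (0 and 4) and clock genes (1 and 0). With the block 7 clock genes rose and 2 fell. Medians of the auxin, reference, root and stomatal lists (0.05, 0.02, 0.02 and 0.04) changed sign with upper-quartile scaling.

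In mapkkk5, 7308 genes changed with chitin, 4019 up and 3289 down, of which 1387 and 501 changed at least 2-fold, and the blocked count was 9896. Upper-quartile scaling gave 3347 up and 4355 down, a shift from 55.0% to 43.5% up.

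**Figure D2:**
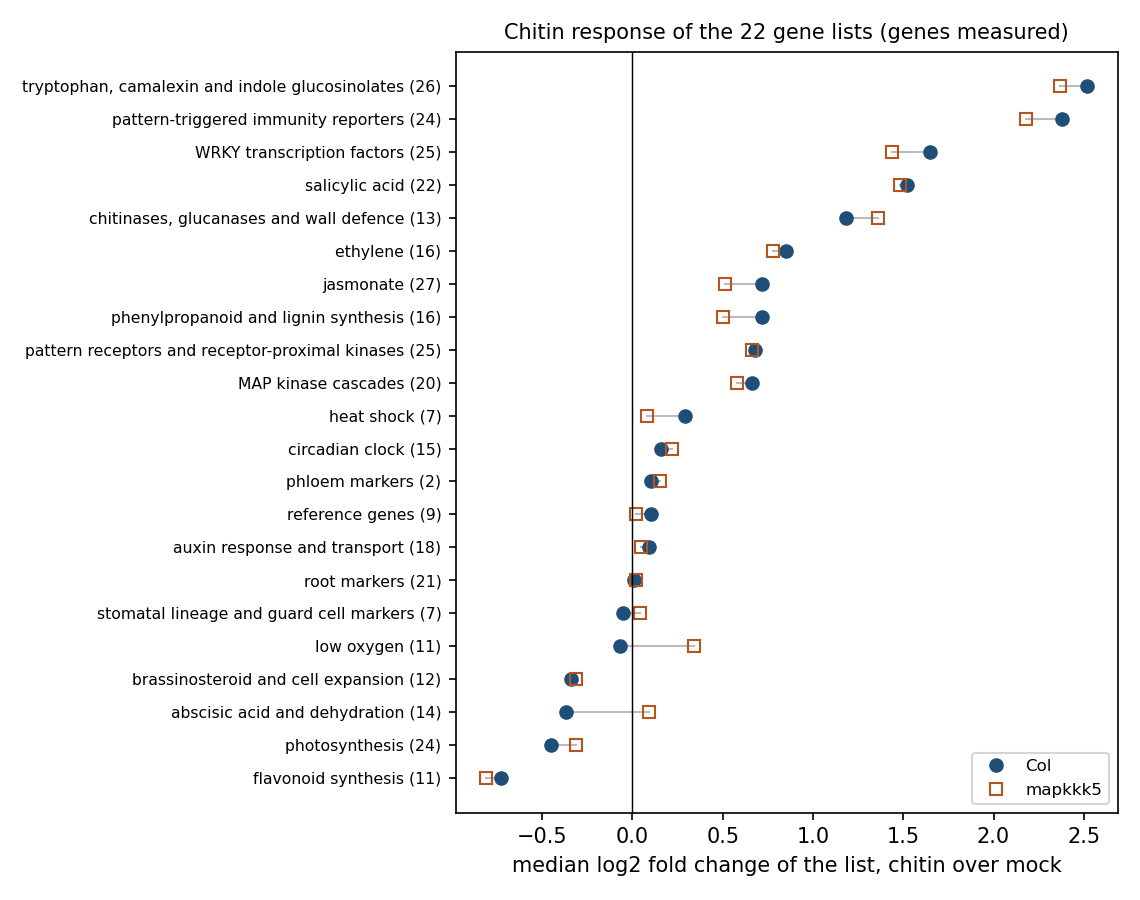
Median log2 fold change by chitin of each of the 22 gene lists (vertical axis, with the number of genes measured), in Col (filled circles) and mapkkk5 (open squares), with grey lines joining the genotypes. The tryptophan and camalexin list is highest, at 2.52 in Col and 2.37 in mapkkk5, and flavonoid synthesis is lowest, at -0.73 and -0.81.

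Whether the mutation changed the chitin response was tested directly. The calls of the separate comparisons overlapped widely, with 3647 genes raised and 2761 lowered in both genotypes, against 853 and 568 for independent lists, and 1 gene changed in opposite directions. No gene passed the test of the difference between the responses in edgeR (275 genes had an unadjusted p under 0.05, where 1050 would by chance). The unblocked p-values hold the spread between experiments too (common dispersion 0.0216, against 0.00883 with the block). A count below that of chance therefore does not speak for equal responses. The lowest p among list members was that of PBS3, with a response smaller by 1.62 ± 0.25 in mapkkk5 (log2; adjusted p = 0.168), followed by ACS2, with -1.84 ± 0.32 (adjusted p = 0.369). With the experiments as a block 2 genes passed, PBS3 (adjusted p = 0.0106) and AT5G25260 (0.013), and DESeq2 called 6, which were ACS2, ICS1, PBS3, AT5G25260 and AT5G52760 with smaller responses and MAPKKK5 with a larger one. Those not in the lists were named after their values were seen. Leaving out Col chitin replicate 2 gave 2 genes, and leaving out mapkkk5 chitin replicate 3 gave 1.

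Salicylic acid genes had the lowest list p for the difference of responses, with a median of -0.13 and a smaller response in mapkkk5 for 14 of 22 (3 over the list alone, camera adjusted p = 7.17e-07, adjusted p = 0.251 with an estimated correlation). Ethylene genes lay at -0.13 (1 over the list alone, 0.000672, adjusted p = 0.31 with an estimated correlation) and brassinosteroid and cell expansion genes at 0.18 (0.000672, adjusted p = 0.251 with an estimated correlation). Camera also passed the WRKY (-0.11, adjusted p = 0.0317), MAP kinase (-0.04, 0.0392), jasmonate (0.00, 0.0463), root (-0.16, 0.036), photosynthesis (0.15, 0.0317) and low oxygen (0.32, 0.0317) lists, none of them with an estimated correlation (adjusted p = 0.577 for the MAP kinase and root lists and 0.628 for the others). With the block, at the preset correlation, the jasmonate list no longer passed (0.0518) and the phenylpropanoid list did (0.00462, against 0.0543 without it). The other 12 lists did not pass, with pattern-triggered immunity reporters at -0.02 (camera adjusted p = 0.448) and tryptophan and camalexin genes at -0.08 (0.661).

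**Figure D3:**
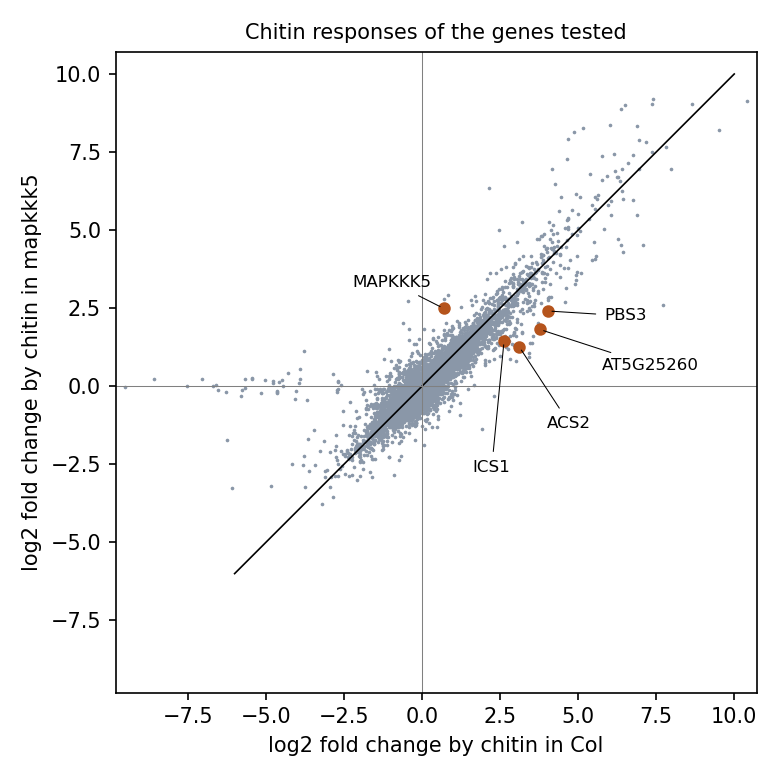
Log2 fold change by chitin in Col (horizontal axis) and mapkkk5 (vertical axis) for the 20994 genes tested, with the line of equal change and 5 genes marked. The points lie along the line (Pearson's r = 0.90 across genes, which are not independent replicates), with PBS3, ACS2, ICS1 and AT5G25260 below it and MAPKKK5 above it. A horizontal band of genes low in Col chitin and near 0 change in mapkkk5 holds seed storage genes such as CRU3, with 99.9% of its reads in 5 of the 12 libraries.

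A general weakening of the response was tested over genes chosen by their chitin response averaged over both genotypes. That average changed 10954 genes, 5661 up and 5293 down (4529 and 6742 with upper-quartile scaling, or 40.2% up in place of 51.7%). Among the 1496 genes raised at least 2-fold, such as PAD3, WRKY33 and MYB51, the median log2 change was 1.72 in Col and 1.60 in mapkkk5, and the median difference of -0.09 did not pass limma's directional fry test (adjusted p = 0.613 over the raised and lowered sets, 0.366 unadjusted). For the 570 genes lowered at least 2-fold, such as IRT1 and GASA5, the medians were -1.34 and -1.27, with a difference of 0.07 (adjusted p = 0.613 in fry). The response was smaller in mapkkk5 for 60.4% of the raised and 59.3% of the lowered genes. Over both sets the slope of the mapkkk5 on the Col changes was 0.99 and Pearson's r across these 2066 genes, which are not independent replicates, was 0.96. Within experiments the median difference of raised genes was -0.19, -0.30 and 0.16 in experiments 1, 2 and 3 (exact sign-flip test, two-sided p = 0.5, where 3 experiments allow 0.25 at the least). Without replicate 3 it was -0.22 (adjusted p = 0.0766 in fry, 0.0486 unadjusted), and without replicate 2 it was 0.01 (adjusted p = 0.966).

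In mock-treated seedlings the genotypes differed in few genes. PR1 (AT2G14610), a salicylic acid marker, was at 123 ± 48.9 CPM in Col and 8.80 ± 5.33 CPM in mapkkk5 (-3.80 ± 0.38, adjusted p = 0.00101). QQS (AT3G30720), a gene linked to starch metabolism, was higher in mapkkk5, 10.5-fold above 1.67 CPM in Col (3.39 ± 0.30, adjusted p = 0.000471), as was MAF5 (AT5G65080), a MADS-box gene of the FLC family, with 6.03 against 0.288 CPM (4.36 ± 0.40, adjusted p = 0.000471). Each of the 3 genes separated all libraries of the genotypes, in mock and in chitin. MAF5 fell outside the rule for named genes and was named after its value was seen. With MAPKKK5 these were the 4 genes that passed, 2 higher and 2 lower, and 463 genes had an unadjusted p under 0.05, where 1050 would by chance. As these unblocked p-values hold the spread between experiments too, the low count does not speak for equal genotypes. Without all 4 libraries of experiment 1, 2 or 3 the count was 0, 2 and 9. The block added NRT1.8, cwINV6 and AT5G35935, all lower in mapkkk5, for a total of 7, and DESeq2 called 7. In Col of experiment 3 AT5G35935 was low as well, at 1.69 CPM in mock and 2.18 CPM in chitin, against 11.9 to 19.9 CPM in Col of experiments 1 and 2 and 0.402 to 2.65 CPM in mapkkk5.

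Among the lists, camera placed several below or above the other genes in mock, none of which held with an estimated correlation in the planned model. Tryptophan and camalexin genes were lower in 24 of 26 cases with none passing over all genes (3 over the list alone; median -0.22, camera adjusted p = 2.71e-13, adjusted p = 0.11 with an estimated correlation). Salicylic acid genes had a median of -0.14, with PR1 passing (1 over the list alone, camera adjusted p = 5.2e-09, adjusted p = 0.11 with an estimated correlation). Chitinase and wall defence genes had a median of -0.24 (1 over the list alone, 5.09e-08, adjusted p = 0.11 with an estimated correlation). Receptor and phenylpropanoid lists lay at -0.10 and -0.07 (camera adjusted p = 0.00454 and 0.0389; adjusted p = 0.53 and 0.777 with an estimated correlation). Flavonoid, abscisic acid and heat shock lists lay at 0.11, 0.21 and 0.46 (0.0179 each, adjusted p = 0.699, 0.51 and 0.51 with an estimated correlation). The other 14 lists had camera adjusted p-values of 0.262 or above. With the seed gene covariate the tryptophan, salicylic acid, chitinase and abscisic acid lists did pass with an estimated correlation (adjusted p = 0.0402 each).

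After chitin, the genes lower in the libraries labelled mapkkk5 included PBS3, ICS1, ACS2 and PR1. PBS3 was at 112 ± 30.4 CPM in Col and 36.9 ± 5.81 CPM in mapkkk5 (-1.61 ± 0.16, adjusted p = 0.000969), from 6.86 and 6.95 CPM in mock. ICS1 (AT1G74710), the isochorismate synthase gene that begins this route, was at 129 ± 28.5 and 58.5 ± 9.71 CPM (-1.14 ± 0.17, adjusted p = 0.0228). The ACC synthase gene ACS2 (AT1G01480), which acts in ethylene synthesis, was at 9.46 ± 2.15 and 2.82 CPM (-1.74 ± 0.20, adjusted p = 0.0019), and PR1 at 231 ± 50.9 and 19.3 ± 3.04 CPM (-3.58 ± 0.37, adjusted p = 0.001). Cell surface kinase genes WAK3 (-1.19 ± 0.18), WAKL10 (-1.15 ± 0.14) and CRK36 (-0.99 ± 0.12) and the U-box gene PUB54 (-1.24 ± 0.16) were lower too, with adjusted p-values of 0.0228, 0.00382, 0.00292 and 0.00535. QQS and MAF5 remained higher, by 3.28 ± 0.32 and 3.94 ± 0.37.

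Of 22 salicylic acid genes, 3 were lower by the test (ICS1, PBS3 and PR1; 10 adjusted over the list alone, 5 with the block, which added EDS5 at -0.73 and FMO1 at -1.08), and all 22 had a negative log2 difference, with a median of -0.32. This list was below the other genes with camera (adjusted p = 5.11e-25), also with an estimated correlation (adjusted p = 0.0126), and not when the block was added to the latter (adjusted p = 0.116). For this list fry gave an adjusted p of 0.00748 (0.0196 with the block), and the fry values of the other lists after chitin are not given here. No other list passed with an estimated correlation in the planned model. With the seed gene covariate the abscisic acid list did (adjusted p = 0.0237). Ethylene genes had a median of -0.22 with ACS2 lower (1 over the list alone, camera adjusted p = 3.02e-06, adjusted p = 0.159 with an estimated correlation), tryptophan and camalexin genes -0.27 with none passing over all genes (5 over the list alone, 2.43e-11, adjusted p = 0.165 with an estimated correlation) and chitinase and wall defence genes -0.26 (0 over the list alone, 0.00197, adjusted p = 0.204 with an estimated correlation). The WRKY, receptor, MAP kinase and phenylpropanoid lists lay at -0.18, -0.20, -0.14 and -0.21 (camera adjusted p = 7.81e-05, 7.81e-05, 0.00197 and 0.000244; adjusted p = 0.204, 0.204, 0.189 and 0.357 with an estimated correlation). The abscisic acid and brassinosteroid lists lay above the other genes, at 0.51 and 0.14 (0.00433 and 0.0107; adjusted p = 0.204 each with an estimated correlation). Over the list alone, the abscisic acid genes COR15A and RAB18 were higher, with an uneven spread over the 3 mapkkk5 libraries (107, 5.75 and 1.78 CPM for COR15A, and 2.39, 6.38 and 23.4 CPM for RAB18). RAB18 was highest, at 6.18 to 23.4 CPM, in the 5 libraries with the most reads of seed storage genes, and at 2.39 CPM or less in the others. Also over the list alone, 1 MAP kinase gene and 2 pattern-triggered immunity reporters were lower, and the latter list had a median of 0.00 (camera adjusted p = 0.629). Root markers had a median of -0.14 (camera adjusted p = 0.0674, with the block 0.0387), and with the block the flavonoid (0.018) and photosynthesis (0.0004) lists lay above the other genes, against 0.109 and 0.0963 without it. All these p-values are at the preset correlation.

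In total 15 genes differed after chitin, 2 higher and 13 lower, and 1276 had an unadjusted p under 0.05 (1050 by chance). The others, named after their values were seen, were AOX1D, AT1G44130, AT4G01870, AT5G25260 and AT5G52760, all lower. The median log2 difference of the 13 lowered genes was -1.33, -1.36 and -0.99 in experiments 1, 2 and 3, with all of them lower in each, which their selection from the same libraries makes nearly certain. With the block 96 genes passed, 11 higher and 85 lower, including all 15, and DESeq2 called 62. Without Col chitin replicate 2 the count was 9, and without all 4 libraries of experiment 1, 2 or 3 it was 0, 4 and 23. With the level of seed storage genes as a covariate, an alternative chosen after the data were seen, 11 of the 15 passed, and ICS1 (-1.28, adjusted p = 0.0521), AOX1D (-1.55, 0.34), AT4G01870 (-0.94, 0.104) and AT5G52760 (-1.06, 0.0892) did not. Their log2 differences were no smaller than without it (-1.14, -1.49, -0.91 and -0.99). The call of ICS1 was lost without Col chitin replicate 1 or 2 (adjusted p = 0.0507 and 0.133) or mapkkk5 chitin replicate 1 or 3 (0.151 and 0.0891), and that of WAK3 without Col chitin replicate 2 or 3 (0.193 and 0.0802) or mapkkk5 chitin replicate 1 or 2 (0.155 and 0.154).

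**Figure D4:**
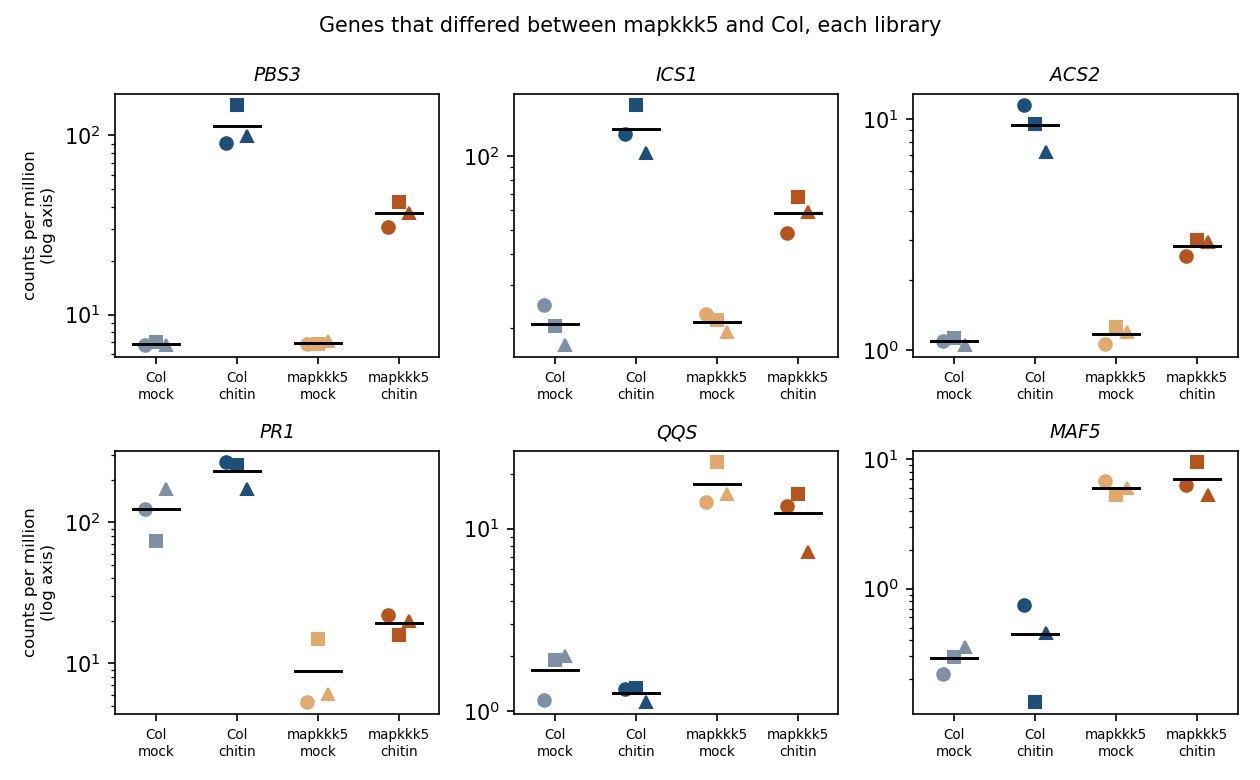
CPM of 6 genes in each library (logarithmic vertical axes) for the 4 groups; circles, squares and triangles are experiments 1, 2 and 3 and black bars are means of 3 libraries. PBS3, ICS1 and ACS2 separate the genotypes after chitin, with PBS3 at 112 CPM in Col and 36.9 CPM in mapkkk5, and PR1, QQS and MAF5 separate them in mock as well.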

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

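The tests of explanations and of other splits in this part had their expectations written after the results were seen. The difference of chitin responses between the genotypes was planned and brought the items below here. The exceptions are MRD1 and AT4G16940, found in a search for genes low or high in 1 experiment, and AT5G35935, seen in values per library.

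In MAPKKK5 itself the response to chitin was larger in the libraries labelled mapkkk5 than in Col, by 1.79 ± 0.36 on the log2 scale (unadjusted p = 0.000206 for the gene alone in edgeR's negative binomial quasi-likelihood test, adjusted p = 0.866; exact sign-flip test over 3 experiments, p = 0.25, the smallest it can give), since its reads returned towards the Col level after chitin. Col RNA in these libraries, by mixing or exchanged labels, would move PR1, QQS and MAF5 towards Col chitin by the same share as MAPKKK5 (54.9%), but their median move was 4.72% (PR1 4.72%, QQS 33.4%, MAF5 -18.6%), and 0.425 to 11.9% within single experiments, although in experiment 3 QQS moved by 56.1% and MAPKKK5 by 23.6%. A chitin effect on the whole stretch of chromosome is argued against by the 10 nearest measured genes, whose median difference of responses was 0.00, from -1.49 to 2.26. The weakly expressed AT5G66830, 2879 bases away, was at the upper end. It resembled MAPKKK5, with -1.76 in mock (not called) and a rise of 1.84 with chitin in mapkkk5 (adjusted p = 0.00606), against -0.42 in Col. AT5G66840, which lies between these genes, was at -0.09. An effect on single neighbours is not excluded by the median. A chitin-dependent transcript from the disrupted gene, of full length or not, may remain as an explanation, and the position of the reads within the gene was not analysed here. The difference is in the gene that defines the genotype, so whether MAPKKK5 function is absent in the chitin-treated libraries stays open.

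PBS3 and AT5G25260 had smaller responses in mapkkk5 with the experiments as a block (adjusted p = 0.0106 and 0.013), and PBS3, ICS1 and PR1 were among 13 genes lower after chitin. A much weaker chitin exposure of mapkkk5 in all experiments is argued against by the slope of 0.99 of the mapkkk5 on the Col response. Genes with large log2 changes weigh most in this slope, and some of them were near 3 reads in mock. The response was smaller in mapkkk5 for 60.4% of the raised and 59.3% of the lowered genes, so a slightly weaker exposure is not excluded. With a replicate number left out the slope ranged from 0.91, without replicate 3, to 1.04. The median difference of raised genes was -0.19, -0.30 and 0.16 in experiments 1, 2 and 3. A slightly weaker exposure in experiments 1 and 2 is therefore not argued against. Since AT4G16940 and MRD1 set Col of experiment 3 apart (next paragraph), an altered Col stock in experiments 1 and 2 was tested too: the 20 genes called lower without replicate 3 had a median difference of -0.85 in experiment 3, with 17 lower, which argues against it. The difference of responses was not negative for all 13 genes. It was 0.22 ± 0.49 for PR1, also low in mock, 0.16 for WAKL10 and 1.43 for AOX1D, none passing the test. In mapkkk5 mock WAKL10 was at 0.173 CPM and AOX1D at 0.0208 CPM, near or below the value of 3 reads. The values of WAKL10 and AOX1D therefore do not settle whether these genes responded less. An effect of MAPKKK5 on the responses of PBS3 and AT5G25260 may explain their part, and so may other changes carried by the mapkkk5 line, as 1 line was studied.

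In Col of experiment 3, MRD1 (AT1G53480) was at 1.05 and 3.3 CPM in mock and chitin, against 56.6 to 76.0 CPM in the other 10 libraries. AT4G16940 was at 1.05 and 1.47 CPM there, against 15.8 to 30.0 CPM in Col of experiments 1 and 2 and 1.28 CPM or less in mapkkk5. AT5G35935 was at 1.69 and 2.18 CPM there, against 11.9 to 19.9 CPM and 0.402 to 2.65 CPM. Libraries of mapkkk5 carrying the name Col would explain AT4G16940 and AT5G35935 but are argued against by PR1, QQS, MAF5 and MAPKKK5, for which 8 of 8 values in these libraries lay nearer to Col of experiments 1 and 2. A different batch of Col seeds in that experiment may explain all 3 genes, and was not tested.

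Other items differed between the genotypes by camera with a preset correlation. The adjusted p-values for the difference of responses were 7.17e-07 for salicylic acid, 0.000672 for ethylene, 0.000672 for brassinosteroid and cell expansion, 0.0317 for WRKY, 0.0317 for photosynthesis, 0.0317 for low oxygen, 0.036 for root markers, 0.0392 for MAP kinase and 0.0463 for jasmonate genes, and none of these lists passed with an estimated correlation. MAPKKK18 changed in opposite directions in all 3 experiments, with a mean log2 change of -0.78 in mapkkk5 and 0.29 in Col, at below 1 CPM, and its difference did not pass edgeR's test (unadjusted p = 0.0848).

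Other splits of the same libraries were fitted in the same way. Of the 10 splits of the 6 libraries of each comparison of 2 groups, 1, the real one, gave as many genes for chitin in Col (8083, highest other 0), chitin in mapkkk5 (7308, highest other 0), genotype in mock (4, highest other 0) and genotype in chitin (15, highest other 1), and 10 splits are too few for a share under 0.05. For the average response 1 of 100 splits drawn gave as many (10954, highest other 0). Nearly all other splits put chitin and mock libraries into the same group, so the chitin effect itself became spread. Low counts were therefore built in, as in the splits of the chitin comparisons, and no conclusion about chance is drawn from them. For the difference of responses the real split gave 0 genes in edgeR (275 at an unadjusted p under 0.05, 6 by DESeq2), so 100 of 100 splits gave as many, with 14 as the highest other count. With a real count of 0 this comparison says nothing about chance, and what raised the count of single splits was not tested.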

How the results depend on the processing

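The alternatives in this part were planned, except the seed gene covariate, chosen after the data were seen. RLE and upper-quartile scaling, the stricter filter and leaving out organelle genes kept every count of the 6 comparisons within 1.5 times its value, as did fitting the compared groups alone for the 4 comparisons of 2 groups. A test against a log2 fold change of 1 gave 949 genes for chitin in Col, 771 in mapkkk5, 1106 on average and 3 between genotypes in chitin, fewer because it asks for a larger change. The block gave 7 genes between genotypes in mock, 96 in chitin and 2 for the difference of responses, as it removes the spread between experiments (common dispersion 0.0216 without it, 0.00883 with it). DESeq2 gave 7, 62 and 6, and no low-count filter 23 in chitin and 1 for the difference of responses; the cause was not tested. The seed gene covariate gave 11 genes between genotypes in chitin, all among the 15, and 4, 0, 7404, 6923 and 10384 in mock, for the difference of responses (edgeR), in Col, in mapkkk5 and on average.

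Leaving out libraries or replicate numbers, which leaves fewer samples, gave 5385 to 7462 genes for chitin in Col, 4762 to 6826 in mapkkk5, 8684 to 10887 on average, 0 to 9 between genotypes in mock, 0 to 23 in chitin and 0 to 2 for the difference of responses. Both genotype counts were 0 without replicate 1 and highest without replicate 3. The median difference of responses ranged from -0.22 to 0.01 for raised genes, reversing without replicate 2, and from 0.03 to 0.12 for lowered genes. It reversed to -0.03 for lowered genes chosen in mapkkk5 alone, a choice that favours large changes there. MAPKKK5 in mock ranged from -2.70 to -2.45 in the 6 refits without 1 library. Without replicate 1 no gene passed in mock, so the call of MAPKKK5 was lost there.

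Of 152 results on named genes, none changed with RLE scaling or no filter, 2 passed in addition with DESeq2 and 1 with the block. These were results called in the main fit, with MAPKKK5 and the difference of responses of PBS3 included in any case. Calls gained elsewhere, such as EDS5 and FMO1 after chitin with the block, were not among them. In 924 refits of the 152 results without 1 library, 71 no longer passed, 2 passed in addition and none reversed. The 57 list results compared were those that passed camera at the preset correlation in the main fit, with the block or with RLE scaling. Of these, 37 no longer passed with an estimated correlation, 5 passed in addition with the block and 1 no longer did, and 1 passed in addition with RLE scaling. Depth limits genes near 0.149 to 0.194 CPM, the value of 3 reads.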

Other observations

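The linkage test, the groups by gene symbol and the choice to look at seed genes came after the results were seen. The bounds of the seed gene tests were written before their values.

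Genes called between the genotypes may gather around MAPKKK5 because sequence linked to the allele differs between the lines. With the experiments as a block, 5 of 334 genes within 1000000 bases of MAPKKK5 differed after chitin (AT5G64870, MAF4, MAF5, DAR3 and AT5G67340), against 91 of 20547 elsewhere (one-sided Fisher exact p = 0.019). MAF4 and MAF5 are adjacent genes, and FLC of their family, at 3173382 on chromosome 5, was also higher (2.26, adjusted p = 0.0472). AT5G64870, DAR3 and AT5G67340 rose with chitin in Col (2.69, 2.30 and 2.55) and were lower in mapkkk5, as were 85 of the 96 genes called with the block. Without the block 1 of the 334 near genes, MAF5, differed, against 14 elsewhere (the same exact test, p = 0.215). The result therefore depends on the block, and the fit that decides it was chosen with the data seen.

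Named genes outside the lists were grouped by the leading letters of their symbols, which need not mark a gene family. Of 119 such groups with at least 10 measured members, CRK kinase genes rose with chitin in 29 of 38 cases in Col (1 fell; median 0.99, camera adjusted p = 7.97e-13), autophagy genes named ATG in 15 of 18 (median 0.55), and FLA arabinogalactan protein genes fell in 11 of 14 (median -0.78). In mapkkk5, CRK genes rose in 26 of 38 cases (median 0.92). After chitin 34 of 38 CRK genes were lower in mapkkk5, with 1 passing the test (median -0.23, camera adjusted p = 1.14e-10). None of these groups passed with an estimated correlation.

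Seed storage and late embryo genes, such as CRU3, with 99.9% of its 2904 reads there, had most of their reads in 5 libraries (Col mock 1, mapkkk5 mock 1 and 3, mapkkk5 chitin 2 and 3). The summed level of 18 such genes was 38.5 to 141 CPM in these and 3.51 to 5.62 CPM in the other 7. Ungerminated seeds among the seedlings may be the source. Of 7 seed genes whose counts had not been looked at, 4 had at least 80% of their reads in the 5 libraries, where 5 were set to speak for seeds and 2 against, and SESA4 (66.9%), OLEO4 (50.5%) and OLEO5 (52.5%) did not, so the source stays open.

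Since 4 of the 5 libraries are of mapkkk5, the seed gene level was tested as the cause of 3 list medians by adding it to the model. The abscisic acid list after chitin stayed at a median of 0.52 (0.51 without it), with a camera adjusted p of 0.0237 with an estimated correlation (0.204 without it). The heat shock list in mock stayed at 0.38 (0.46) and passed with an estimated correlation neither with the covariate (adjusted p = 0.466) nor without it (0.51). The salicylic acid list after chitin stayed at -0.38 (-0.32), with a camera adjusted p of 0.0159 with an estimated correlation. The covariate is linear on the log2 scale, and a median need not move where seed reads reach only some members. In this form the values argue against the seed gene level as the whole cause of any of the 3 medians, of which that of heat shock was weak to begin with. They do not speak for single members such as RAB18.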
